A study of Homo sapiens with 30 samples.

How the data were processed

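Gene expression was measured by QuantSeq 3′ tag sequencing in 30 libraries of 3 colorectal cancer cell lines, in 10 groups of 3. Per the labels, cells were transduced with hairpin vectors and selected with puromycin, and the differentiation medium, with troglitazone (10 uM) and 1α,25-dihydroxyvitamin D3 (25 nM), was given from 3 days after transduction. The authors deposited 1 table per library, with raw counts per gene symbol. Per the submitters' processing notes, Bowtie2, edgeR and the genome hg19 were used, without versions or settings, so how tags were assigned to genes that share sequence or overlap is not stated. The deposited values were checked to be whole numbers. Of 25737 symbols listed per table, 1561 lines belonging to 286 symbols repeated a symbol and were summed, leaving 24462 symbols. Every column was used. Transcript GC content and gene positions came from GENCODE 29 on GRCh38, as no hg19 annotation was at hand.

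Each cell line was fitted on its own with all its groups in edgeR 4.0.16 under R 4.3.3 (filterByExpr, TMM factors, robust dispersions, quasi-likelihood F tests). Tested genes numbered 13968 in Caco2, 13279 in HCT116 and 13252 in SW480, and a gene was called at 5 percent FDR over them. SE is the log2 fold change divided by the square root of F. There were 10 main and 2 secondary comparisons, the latter against scramble cells in differentiation medium. The step between fractions was compared between lines as an interaction in a joint fit of 2 lines, with 1 dispersion per gene for both. No replicate block was used. Levels are CPM with TMM factors, given as mean and SD of 3 libraries, fold changes are ratios of these means, and log2 fold changes are fitted values. Where a group had 0 counts, a bound was computed from 3 counts over the group, and with 1 to 3 counts a 95 percent counting interval is given.

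Groups of genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison, with at least 3 tested members. The 24 lists were colonocyte, goblet, enteroendocrine, tuft and Paneth, stem cell and Wnt targets, PPAR targets, VDR targets, G2M and mitosis, DNA replication, interferon response, germline, H3K9 methylation, cholesterol synthesis, p53 targets, mesenchymal, immediate early and heat shock, ATF4 and unfolded protein, leukocyte and fibroblast, hypoxia and glycolysis, and, by symbol pattern, ZNF, clustered protocadherins, ribosomal proteins, histones and genes of the mitochondrial genome. The last has 0 members in these tables and gives no result. The comparisons, lists, alternatives and the rule for named genes were set before the data were examined. By that rule SETDB1 and KRT20 are named in every comparison. Each main comparison names from the 8 called genes per direction with the largest log2 fold change, a mean of at least 10 CPM in the higher group and no overlap of the 6 libraries. Each list names from its 4 members with the smallest adjusted p. Each difference between lines names from the 5 genes per direction with the smallest adjusted p and at least 10 CPM in the highest group. Secondary comparisons name only SETDB1, KRT20 and list members. For length, not every gene the rule allows is printed, a choice made with the values in view, and some genes are not reported here.

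Library totals ran from 5349737 to 10221854 counts. Replicates in HCT116 and SW480 varied far more than counting error: the chi-square per degree of freedom between replicates was 2.208 to 16.26 in Caco2, 37.62 to 89.48 in HCT116 and 41.16 to 138.3 in SW480. In those 2 lines the trend of expression with transcript GC content (7845 genes with a mean of at least 20 CPM) parted the libraries into an AT and a GC class, a grouping made after seeing the data. The AT class holds HCT116 KRT-negative replicate 1, KRT-positive replicates 1 to 3 and unsorted replicates 1 and 2, and replicate 2 of each SW480 group.

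The procedure was tested on simulated data drawn from the gene means, library sizes and dispersions of each line, with 100 genes changed at each fold. edgeR recovered 80% of 2-fold and 92% of 4-fold changes in Caco2, 0% and 35% in HCT116, and 3% and 25% in SW480, with 5, 0 and 1 unchanged genes called. For the difference of Caco2 and HCT116 edgeR recovered 0% and 10%. DESeq2 1.42.0 recovered 42% and 46% of 4-fold changes in HCT116 and SW480, with 46 and 57 unchanged genes called. The alternatives were RLE size factors, library totals, no low-count filter, DESeq2, a replicate block, only the 2 groups compared, each library left out in turn and an estimated correlation. The GC class as a term or as a subset, and leaving out libraries in the overlaps, were added after seeing the data. Repeat elements, which SETDB1 silences, were not analysed here.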

Results

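QuantSeq, which reads a tag near the 3′ end of each polyadenylated transcript, measured gene expression in 30 libraries of the colorectal cancer lines Caco2, HCT116 and SW480, in 10 groups of 3. SETDB1 encodes a methyltransferase that places trimethyl marks on lysine 9 of histone H3 and silences genes and repeats. KRT20 encodes an intermediate filament keratin of mature gut epithelium. In Caco2, cells with a scrambled hairpin in vehicle or in differentiation medium (troglitazone, an agonist of the receptor PPARG, and 1α,25-dihydroxyvitamin D3, the ligand of the vitamin D receptor VDR) stand beside SETDB1-hairpin cells sorted as KRT20-negative or KRT20-positive. In HCT116 and SW480, SETDB1-hairpin cells sorted as KRT-negative or KRT-positive stand beside unsorted cells. The labels do not say in which medium the SETDB1-hairpin and unsorted cells grew, which hairpin the unsorted cells carried, or whether replicates were separate cultures, so the p-values measure the spread between these samples. The libraries held 6538087 to 10074838 counts in Caco2, 5349737 to 10221854 in HCT116 and 6915326 to 10036179 in SW480. So 3 counts, the level a count of 0 allows under counting error alone, are 0.293 to 0.561 CPM (counts scaled to a common total). HCT116 and SW480 replicates varied more, so minimum folds and counting intervals there are not firm. Replicates correlated at a Spearman coefficient of 0.970 to 0.992 across genes in Caco2, 0.822 to 0.866 in HCT116 and 0.748 to 0.886 in SW480 (genes are not independent replicates).

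SETDB1 (chromosome 1, 150926263 to 150964744, GRCh38) is the gene the hairpin targets, and the 3′ tag counts its polyadenylated transcript, not its protein. In Caco2 it stood at 30.7 CPM (SD 1.71, n = 3) in vehicle and 34.2 (SD 3.21) in differentiation medium, against 21.4 (SD 2.17) in KRT20-negative and 23.0 (SD 3.17) in KRT20-positive SETDB1-hairpin cells. All 6 SETDB1-hairpin libraries lay below all 6 scramble libraries. Against vehicle it fell in the KRT20-negative fraction by 0.52 on the log2 scale (edgeR adjusted p = 0.00231) and in the KRT20-positive fraction by 0.42 (edgeR adjusted p = 0.0119, but 0.081 without KRT20-positive replicate 1). In HCT116, unsorted cells had 53.4 CPM (SD 31.7), KRT-negative cells 2.90 (SD 2.87) and KRT-positive cells 17.8 (SD 14.7). The KRT-negative drop was called (log2 −4.19, edgeR adjusted p = 0.0424), and lost without KRT-negative replicate 3 (0.161), unsorted replicate 1 (0.136) or unsorted replicate 2 (0.119). The KRT-positive value was not called (edgeR adjusted p = 0.407). In SW480, unsorted cells had 28.9 CPM (SD 12), KRT-negative cells 13.2 (SD 19.9) and KRT-positive cells 4.02 (SD 6.96), and neither fraction was called against unsorted (edgeR adjusted p = 0.938 and 0.523, the latter 0.0496 without KRT-positive replicate 3). KRT-negative replicate 1 of SW480, at 36.1 CPM, lay above every unsorted SW480 library, so depletion at the transcript level is not shown in that library.

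KRT20 (chromosome 17, 40875941 to 40885227, GRCh38) is the gene the sort is named after, so its difference between fractions checks the labels and is no result. In Caco2 it stood at 1.01 CPM (SD 0.211, n = 3) in vehicle, 7.68 (SD 1.45) in differentiation medium, 1.30 (SD 0.399) in KRT20-negative and 32.9 (SD 6.20) in KRT20-positive cells. In SW480 it stood at 57.7 CPM (SD 15.8) in KRT-positive cells, 0.222 in KRT-negative cells and 0 in unsorted cells. In HCT116 it was seen in 1 of 3 KRT-positive libraries (5.84 CPM in replicate 3, 0 in the others), was listed at 0 in KRT-negative cells and at 0.386 CPM in unsorted cells, and was too low to test. The HCT116 labels write KRT, not KRT20, and these counts do not show which keratin that sort used.

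**Figure D1:**
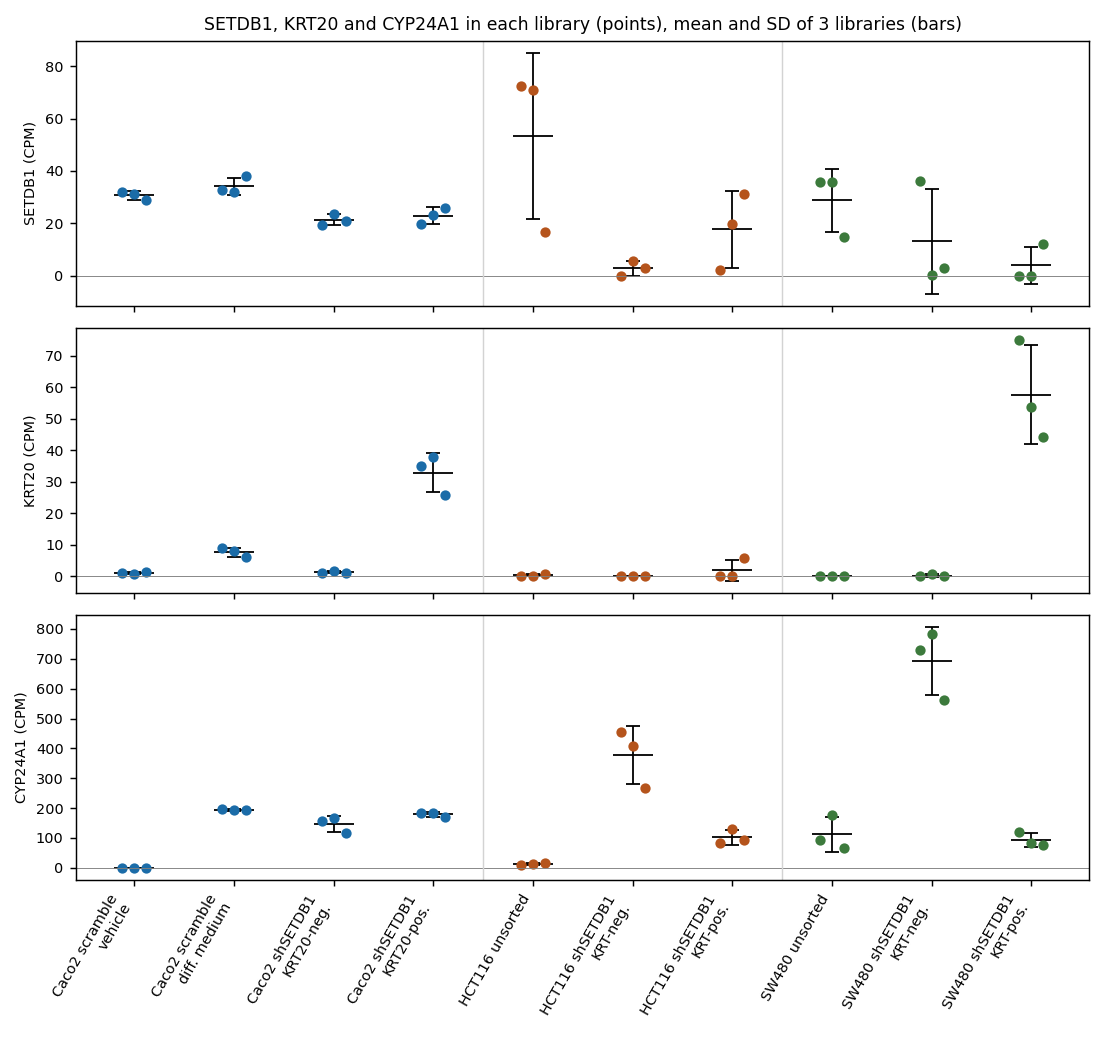
The plot gives SETDB1, KRT20 and CYP24A1 in CPM on linear axes for each library (points), with the mean and SD of the 3 libraries of each group (bars).

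Differentiation medium against vehicle in scramble Caco2 cells asks what the agonists alone did. The medium raised the targets of both receptors and hypoxia and glycolysis genes, and lowered cholesterol synthesis, crypt stem cell and goblet genes. CYP24A1, the hydroxylase that degrades vitamin D and a direct VDR target, rose from 0.622 CPM (SD 0.357, n = 3) to 194 (SD 2.89). At 5 percent FDR edgeR called 2925 of 13968 tested genes, 1454 higher and 1471 lower, 465 of them by at least 2-fold. Of all tested genes, 39.1% had no overlap between the 3 libraries of each group, where chance gives 10%. VDR targets had 11 of 22 members higher and 0 lower over all genes, 12 and 1 adjusted over the list alone (median log2 0.95, 0.88 with the 2 genes that had a group at 0 counts set at their bounds). They included SLC37A2 (5.20-fold) and CLMN (4.38-fold). PPAR targets had 14 of 26 members higher and 1 lower over all genes, the same numbers adjusted over the list alone, with CPT1A at log2 2.11 (SE 0.08) and the lipid droplet coat PLIN2 at 1.69 (SE 0.08). SAA1, an acute phase protein, rose 76.2-fold, the homeobox gene HOXB8 9.22-fold, the chemokine CCL20 8.03-fold, CLDN2, a pore-forming claudin, 7.89-fold and CEACAM6, an adhesion molecule of colonocytes whose reads its paralogs can share, 11.3-fold. The colonocyte list as a whole was split (8 of 27 higher and 8 lower over all genes, 11 and 10 adjusted over the list alone).

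Of 25 cholesterol synthesis genes 21 fell over all genes and 21 adjusted over the list alone (median log2 −0.69), with the SREBP regulator INSIG1 at log2 −1.25 (SE 0.09), mevalonate kinase MVK at −1.16 (SE 0.10) and squalene epoxidase SQLE at −0.97 (SE 0.11). Wnt and stem cell target genes fell with them (12 of 24 lower and 2 higher over all genes, 13 and 2 adjusted over the list alone). The Wnt inhibitor DKK1 fell by 1.41 on the log2 scale, the stem cell factor ASCL2 by 0.99, the Wnt feedback gene NKD1 by 0.98 and the ligand BMP4 by 0.80. Goblet genes had 5 of 13 lower over all genes, 5 lower and 1 higher adjusted over the list alone, with the peptides TFF3 2.17-fold and TFF1 1.74-fold lower. The single genes SERPINF2, FGG, FGA, CPS1, ITIH2 and ALB fell between 5.15-fold and 3.36-fold. Hypoxia and glycolysis genes rose (11 of 28 higher and 1 lower over all genes, 13 and 2 adjusted over the list alone), led by the stress gene NDRG1 (3.03-fold) and the glucose transporter SLC2A1 (2.59-fold). Immediate early and heat shock genes rose (13 of 29 higher and 2 lower over all genes, 14 and 2 adjusted over the list alone), as did ATF4 and unfolded protein genes (8 of 28 higher and 3 lower over all genes, 12 and 3 adjusted over the list alone), among them DDIT4, an inhibitor of mTOR (2.98-fold). The lists named so far as changed were called by camera at a preset correlation of 0.01 and held with an estimated one. Ribosomal protein genes (37 of 78 higher and 1 lower over all genes, 41 and 1 adjusted over the list alone, RPS29 1.57-fold higher) had a camera adjusted p = 0.0698 with an estimated correlation. Germline genes (1 of 7 higher and 1 lower over all genes, 2 and 1 adjusted over the list alone) and leukocyte and fibroblast markers (1 of 12 higher over all genes and adjusted over the list alone) were not called. Mitosis genes split evenly (6 of 32 higher and 7 lower over all genes, 7 and 7 adjusted over the list alone, with a median log2 of 0.00, a mean of −0.01 and a test that pointed down).

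SETDB1-hairpin Caco2 cells of the KRT20-negative fraction against scramble cells in vehicle ask what SETDB1 depletion does in cells that did not turn on KRT20. Enterocyte and enteroendocrine genes and the targets of VDR and PPAR rose, and cell division, cholesterol synthesis and crypt stem cell genes fell. Because the medium of the SETDB1-hairpin cells is not stated, hairpin and medium are not separated here. In edgeR 5056 genes were called, 2601 higher and 2455 lower, 1200 by at least 2-fold, and 44.7% of tested genes had no overlap between the groups (chance, 10%). GC, the carrier of vitamin D in plasma, rose 132-fold from 0.376 CPM to 49.6, CYP24A1 235-fold and SAA1 103-fold. UGT1A1, which conjugates bilirubin and shares its 3′ end with the other UGT1A genes, rose 101-fold on 3 vehicle counts (counting interval 34.1 to 490). Of 22 VDR targets 17 rose and 1 fell over all genes, 18 and 1 adjusted over the list alone (median log2 1.58, 1.28 with 2 genes at their bounds). PPAR targets had 13 of 26 higher over all genes and 13 adjusted over the list alone, with CPT1A at log2 1.57 (SE 0.08), TXNIP, a brake on glucose uptake, at 1.52 (SE 0.11) and PLIN2 at 1.06 (SE 0.08). Enteroendocrine genes had 6 of 9 higher over all genes and 7 adjusted over the list alone, with PAX4 at 0 in vehicle and 7.69 CPM (SD 1.08) here, at least 56.9-fold higher, and INSM1 52.2-fold higher. Colonocyte genes had 11 of 27 higher and 3 lower over all genes, 12 and 3 adjusted over the list alone, with FABP1, which binds fatty acids, 16.6-fold, APOB 3.26-fold and APOA1 2.40-fold higher. The list of KRAB-type and other ZNF zinc finger genes, a class that SETDB1 marks, had 122 of 404 higher and 12 lower over all genes, the same numbers adjusted over the list alone (median log2 0.33), with ZNF69 18.4-fold, ZNF117 15.8-fold and ZNF91 4.09-fold higher. ATF7IP, the partner that stabilises SETDB1, rose 3.04-fold (edgeR adjusted p = 4.83e-14, 3 of 3 libraries higher), within a list of H3K9 methylation genes of which 10 of 23 fell and 2 rose over all genes, 10 and 2 adjusted over the list alone.

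In the same comparison all 32 mitosis genes fell over all genes and adjusted over the list alone (median log2 −0.64), CDK1 of mitotic entry 2.17-fold and its cyclin CCNB1 1.81-fold. DNA replication genes had 19 of 32 lower over all genes and 21 adjusted over the list alone. Cholesterol synthesis had 22 of 25 lower and 2 higher over all genes, 22 and 3 adjusted over the list alone, with INSIG1 3.72-fold lower. Stem cell and Wnt target genes had 15 of 24 lower and 3 higher over all genes, 16 and 3 adjusted over the list alone. DKK1 fell by 2.96 on the log2 scale, BMP4 by 1.75, cyclin D1 (CCND1) by 0.69 and ASCL2 by 0.68. SLC2A3, a neuronal glucose transporter whose reads SLC2A14 can share, fell 14.4-fold from 2309 CPM, within a hypoxia and glycolysis list that fell (12 of 28 lower and 5 higher over all genes, 14 and 7 adjusted over the list alone) although NDRG1 rose 4.26-fold. ATF4 and unfolded protein genes fell (12 of 28 lower and 4 higher over all genes, 13 and 4 adjusted over the list alone), with asparagine synthetase ASNS 2.93-fold lower. The lipoprotein receptor OLR1 fell 24.5-fold, the actin-binding TAGLN 19.7-fold and the natriuretic peptide NPPB 19.5-fold. The lists named here as changed held with an estimated correlation, as did tuft and Paneth genes (1 of 5 higher over all genes and 1 adjusted over the list alone), a call that rests on the Paneth phospholipase PLA2G2A (12.8-fold higher), since the median was −0.07 while the mean (0.60) and the test pointed up. Interferon response genes (10 of 23 higher and 1 lower over all genes, 11 and 1 adjusted over the list alone) were called at the preset correlation, but the camera adjusted p = 0.217 with an estimated correlation and 0.114 without KRT20-negative replicate 3. Without that replicate OAS1, which senses double-stranded RNA, was not called either (1.68-fold higher, edgeR adjusted p = 0.00715 with it and 0.0528 without). KRT20-negative replicate 3 also exceeded the other 11 Caco2 libraries in 34 of 48 listed fibroblast genes, not in TAGLN or CALD1 among others, with 264 CPM of COL6A3 (chosen after its values were seen) against 6.45 to 17.4 in the others. The mesenchymal list (4 of 17 higher and 4 lower over all genes, 5 and 4 adjusted over the list alone) had a median of 1.14 and a mean of 0.78 while its test pointed down. P53 targets and germline genes had medians below 0 (−0.01 and −0.21) with means above 0 (0.12 and 0.23) and were not called.

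The KRT20-positive fraction against scramble cells in vehicle asks the same of SETDB1-hairpin cells that did turn on KRT20. Colonocyte, enteroendocrine, VDR and PPAR target genes rose and cell division, cholesterol synthesis and crypt stem cell genes fell. Again hairpin, medium and sort are not separated. In edgeR 5265 genes were called, 2692 higher and 2573 lower, 1401 by at least 2-fold, with 51.3% of tested genes free of overlap (chance, 10%). Colonocyte genes had 17 of 27 higher and 2 lower over all genes, 18 and 2 adjusted over the list alone (median log2 1.09). FABP1 reached 1809 CPM (SD 131, n = 3) against 63.1 in vehicle, CEACAM5, a tumour antigen of colon epithelium, rose 24.7-fold, and APOB 2.83-fold. Goblet genes had 6 of 13 higher and 1 lower over all genes, 7 and 2 adjusted over the list alone, with the mucus protein FCGBP 19.4-fold higher, and a camera adjusted p = 0.0688 with an estimated correlation. Enteroendocrine genes had 7 of 9 higher over all genes and 8 adjusted over the list alone, with PAX4 at least 50.2-fold, INSM1 70.0-fold and the granule protein CHGA 57.5-fold higher, the last on 2 vehicle counts (counting interval 15.6 to 481). VDR targets had 19 of 22 higher and 1 lower over all genes and adjusted over the list alone (median log2 2.08, the same with 2 genes at their bounds), with CYP24A1 at 180 CPM (SD 8.25). PPAR targets had 14 of 26 higher over all genes and 15 adjusted over the list alone, CPT1A at log2 2.51 (SE 0.08). GC rose 202-fold and SAA1 110-fold. ZNF genes had 122 of 404 higher and 14 lower over all genes, 121 and 13 adjusted over the list alone, again with ZNF117, ZNF69 and ZNF91 (18.4-fold, 18.9-fold and 5.36-fold). ATF7IP rose 2.56-fold.

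Among falling genes in KRT20-positive cells, 30 of 32 mitosis genes (30 adjusted over the list alone) included CDK1 and the proliferation marker MKI67, 1.81-fold and 1.76-fold lower, and DNA replication genes fell with them. Cholesterol synthesis had 21 of 25 lower and 1 higher over all genes, 22 and 1 adjusted over the list alone, with INSIG1 3.60-fold lower. Wnt and stem cell target genes had 16 of 24 lower and 1 higher over all genes and adjusted over the list alone, with DKK1 8.20-fold, BMP4 3.56-fold, NKD1 3.29-fold and ASCL2 2.02-fold lower. SLC2A3 fell 29.6-fold, the muscle protein MYBPH 36.2-fold, NPPB 25.0-fold, TAGLN 19.1-fold and SOX2, a pluripotency factor, 10.3-fold. Hypoxia and glycolysis genes and ATF4 and unfolded protein genes (ASNS 3.03-fold) fell. Interferon response genes had 11 of 23 higher over all genes and 13 adjusted over the list alone, with OAS1 3.82-fold higher, and a camera adjusted p = 0.0744 with an estimated correlation. Mesenchymal genes (5 of 17 lower and 3 higher over all genes and adjusted over the list alone) had a camera adjusted p = 0.318 with an estimated correlation and 0.0595 without KRT20-positive replicate 3, and ribosomal protein genes were not stable to the correlation in either fraction. P53 targets were not called (median −0.04 and mean 0.02, with the test pointing down), although the cell cycle inhibitor CDKN1A rose 3.91-fold.

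KRT20-positive against KRT20-negative Caco2 cells, sorted from cells with the same hairpin, asks what goes along with KRT20. Markers of absorptive and goblet cells and targets of PPAR and VDR were higher in the positive fraction, and Wnt and stem cell genes were lower, while SETDB1 itself did not differ (1.07-fold, edgeR adjusted p = 0.766). In edgeR 570 genes were called, 321 higher and 249 lower, 114 by at least 2-fold, but 297 without KRT20-positive replicate 1, 358 without KRT20-positive replicate 2 and 305 without KRT20-positive replicate 3. Of tested genes 19.8% had no overlap (chance, 10%). Apart from KRT20 and the brush border lectin LGALS4, large rises were seen in FCGBP (8.38-fold), CEACAM5 (6.86-fold), MAOA, which degrades monoamines (5.97-fold) and the mitochondrial subunit C15orf48 (3.74-fold). Colonocyte genes had 11 of 27 higher over all genes, 13 higher and 1 lower adjusted over the list alone, CEACAM6 3.27-fold and FABP1 1.73-fold among them. Goblet genes had 5 of 13 higher over all genes and 7 adjusted over the list alone, MUC2 5.37-fold. PPAR targets had 7 of 26 higher over all genes and 9 adjusted over the list alone, with PDK4, which turns cells from glucose to fat, at log2 1.22 (SE 0.22) and CPT1A at 0.94 (SE 0.08). VDR targets had 6 of 22 higher over all genes and 9 adjusted over the list alone, with S100G 7.61-fold, CYP2B6 2.39-fold and SLC37A2 2.00-fold higher. Stem cell and Wnt target genes had 6 of 24 lower over all genes and 9 adjusted over the list alone, with the crypt gene SMOC2 4.92-fold, NKD1 2.63-fold and the Wnt receptor ligase RNF43 1.55-fold lower. LGR5, the crypt stem cell receptor, was 1.92-fold lower (edgeR adjusted p = 0.0166), and not called without any 1 of KRT20-negative replicates 1 and 2 and KRT20-positive replicates 1, 2 and 3 (edgeR adjusted p from 0.0505 to 0.1). Also lower were the basement membrane laminin LAMA1 (8.23-fold), IGDCC3 (2.75-fold), OLFML3 (2.72-fold), the transcription factor TCF4 (2.16-fold) and FGA (2.14-fold). These lists held with an estimated correlation, and so did cholesterol synthesis (2 of 25 lower and 1 higher over all genes, 4 and 1 adjusted over the list alone), whose call went without KRT20-positive replicate 2 (camera adjusted p = 0.0563).

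Other lists in this comparison were less firm. Mitosis genes were slightly higher (2 of 32 over all genes and 2 adjusted over the list alone, median log2 0.07), with a camera adjusted p = 0.0686 with an estimated correlation, and 0.0851, 0.0579 and 0.0729 without KRT20-negative replicate 1, KRT20-negative replicate 3 or KRT20-positive replicate 2. Interferon response genes (1 of 23 higher over all genes and adjusted over the list alone, OAS1 2.28-fold) had a camera adjusted p = 0.207 with an estimated correlation, and 0.358, 0.0765 and 0.0748 without KRT20-negative replicate 1, KRT20-negative replicate 2 or KRT20-positive replicate 1. Mesenchymal genes (2 of 17 lower and 1 higher over all genes and adjusted over the list alone, fibronectin FN1 1.86-fold lower) had a camera adjusted p = 0.221 with an estimated correlation and 0.153 without KRT20-negative replicate 3, the library with the fibroblast genes. Leukocyte and fibroblast markers were called higher only without that library (camera adjusted p = 0.0158), and with it their median was −0.01, their mean −0.78 and their test pointed up. P53 targets were called lower without KRT20-positive replicate 3 (camera adjusted p = 0.0434), and ribosomal protein genes were called lower without KRT20-negative replicate 2 (0.0331). Signs also differed for tuft and Paneth genes (median 0.08, mean −0.11), immediate early genes (median −0.04, mean 0.04) and protocadherins (median −0.10, mean 0.06), none of them called.

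Both SETDB1-hairpin fractions were also compared with scramble cells in differentiation medium, as secondary comparisons that ask whether the medium alone gives the same levels. Neither fraction matched scramble cells in that medium: enterocyte, enteroendocrine and ZNF genes were higher and cell division genes lower in both. In edgeR 5312 genes were called in KRT20-negative cells (2739 higher and 2573 lower, 46.1% of tested genes with no overlap, chance 10%) and 4820 in KRT20-positive cells (2508 higher and 2312 lower, 48.7%). SETDB1 was 1.60-fold and 1.49-fold lower, and KRT20 5.91-fold lower in the negative and 4.28-fold higher in the positive fraction. FABP1 was 8.64-fold and 14.9-fold higher, in a colonocyte list with 12 of 27 higher and 5 lower over all genes in negative cells (12 and 6 adjusted over the list alone) and 16 and 2 in positive cells (16 and 4 adjusted over the list alone). CHGA was at 0 in scramble cells and at least 26.8-fold and 39.5-fold higher, and enteroendocrine genes had 7 of 9 higher in each fraction over all genes and adjusted over the list alone. ZNF genes had 157 of 404 higher and 10 lower over all genes in negative cells (159 and 10 adjusted over the list alone) and 145 and 7 in positive cells (147 and 7 adjusted over the list alone), with ZNF69 16.5-fold and 16.9-fold and ZNF91 7.85-fold and 10.3-fold higher. Mitosis genes had 30 of 32 lower in each fraction over all genes (31 and 30 adjusted over the list alone), CDK1 2.34-fold and 1.95-fold, and DNA replication 16 and 15 of 32 (17 and 15 adjusted over the list alone). Hypoxia and glycolysis genes (SLC2A1 4.37-fold and 3.42-fold) and ATF4 and unfolded protein genes (ASNS 2.97-fold and 3.07-fold) were lower in both. VDR targets had 9 of 22 higher and 4 lower in negative and 13 and 1 in positive cells over all genes (9 and 5, 14 and 2 adjusted over the list alone). Only in the positive fraction were goblet genes (8 of 13 higher over all genes and 9 adjusted over the list alone, FCGBP 57.0-fold) and PPAR targets (11 of 26 higher and 5 lower over all genes, 12 and 5 adjusted over the list alone, PDK4 3.87-fold and TXNIP 2.73-fold higher) called higher. Only there, too, were stem cell and Wnt targets (14 of 24 lower and 1 higher over all genes and adjusted over the list alone, DKK1 3.08-fold and AXIN2 2.22-fold lower) and cholesterol synthesis (13 of 25 lower and 1 higher over all genes, 13 and 2 adjusted over the list alone) called lower. All these calls held with an estimated correlation. In the negative fraction goblet genes had 5 higher and 2 lower, PPAR targets 8 and 6, stem cell and Wnt targets 6 and 9 and cholesterol synthesis 4 and 10 over all genes (4 and 11 adjusted over the list alone, the others the same). Mesenchymal genes were called lower in the positive fraction (5 of 17 lower and 2 higher over all genes and adjusted over the list alone), with a camera adjusted p = 0.253 with an estimated correlation. In the negative fraction they were called lower only without KRT20-negative replicate 3 (camera adjusted p = 0.0341), and goblet genes higher only without that library (0.0461) or without differentiation medium replicate 2 (0.0432). Medians and means above 0 stood beside a test pointing down for mesenchymal (0.53 and 0.59), leukocyte and fibroblast (0.68 and 0.75) and stem cell genes (0.01 and 0.03) in the negative fraction, none called. In the positive fraction leukocyte and fibroblast markers had a median of 0.09 and a mean of −0.03, not called.

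**Figure D2:**
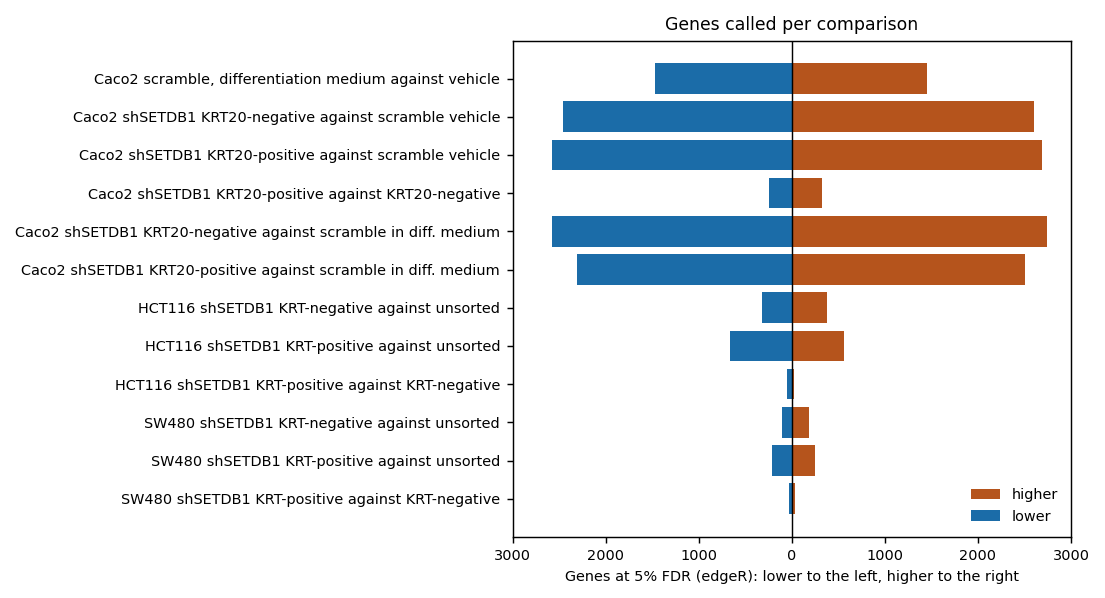
Bars give the number of genes edgeR called at 5 percent FDR in each of the 12 comparisons, lower to the left and higher to the right, on a linear axis.

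KRT-negative SETDB1-hairpin HCT116 cells against unsorted cells ask what goes with SETDB1 depletion, the sort and any agonists in the unstated medium. Cell division genes fell, and targets of VDR, PPAR, p53 and the stress factor ATF4 rose. Samples of HCT116 and SW480 also split by a trend of expression with transcript GC content, so values within each class are given beside the pooled ones (AT class, KRT-negative replicate 1 and unsorted replicates 1 and 2, and GC class, the other 3 libraries of this comparison). In edgeR 698 of 13279 genes were called, 374 higher and 324 lower, 634 by at least 2-fold, against 350 within the AT class and 341 within the GC class, where a lone library is assumed to vary like the others. The count was 395 without KRT-negative replicate 3, 453 without KRT-negative replicate 2, 432 without unsorted replicate 1 and 404 without unsorted replicate 2, and 24.5% of tested genes had no overlap (chance, 10%). CD274, the immune checkpoint ligand PD-L1, was at 38.7 CPM (SD 30.1, n = 3) and had 1 count in unsorted cells, a ratio of 700 (counting interval 125 to 27700). APOL6, an interferon-induced lipid binder, and TSPAN8, an epithelial tetraspanin, also had 1 unsorted count, with ratios of 322 (57.6 to 12800) and 250 (44.6 to 9900), and neither was called within the GC class. VDR targets had 7 of 18 higher over all genes and 8 adjusted over the list alone, with the calcium channel TRPV6 147-fold, CYP24A1 29.1-fold, the cadherin CDH1 8.62-fold and GADD45A 4.85-fold higher. PPAR targets had 5 of 19 higher over all genes and 5 adjusted over the list alone, with ANGPTL4 at log2 5.23 (SE 0.35) and PLIN2 at 3.29 (SE 0.25). ATF4 and unfolded protein genes had 16 of 27 higher over all genes and 17 adjusted over the list alone, with DDIT3 7.57-fold, ASNS 7.48-fold and TRIB3 6.57-fold higher. P53 targets had 7 of 28 higher over all genes, 9 higher and 1 lower adjusted over the list alone, with SESN2 6.57-fold, the stress cytokine GDF15 4.22-fold and CDKN1A 2.44-fold higher. Interferon response genes had 3 of 32 higher over all genes and 9 adjusted over the list alone, with OAS1 62.3-fold and ISG15 2.88-fold higher (camera adjusted p = 0.0505 within the AT class).

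Mitosis genes had 19 of 32 lower over all genes and 27 adjusted over the list alone (median log2 −2.49), with CCNB1 12.6-fold, MKI67 6.11-fold and topoisomerase TOP2A 5.23-fold lower. DNA replication genes had 13 of 32 lower over all genes and 19 adjusted over the list alone, with RRM2 5.68-fold and MCM2 4.83-fold lower. GMNN fell 17.4-fold, PDE4B 22.9-fold and FAM198B 32.7-fold, the last not called without unsorted replicate 1 (edgeR adjusted p = 0.0699). These lists held with an estimated correlation. Wnt and stem cell target genes (2 of 18 lower over all genes and 3 adjusted over the list alone, DKK1 9.39-fold lower) had a camera adjusted p = 0.0747 with an estimated correlation. H3K9 methylation genes (4 of 22 lower over all genes, SETDB1 among them, 7 lower and 1 higher adjusted over the list alone) had a camera adjusted p = 0.0936 with an estimated correlation, 0.0571 without unsorted replicate 1, and 0.0559 and 0.0849 within the AT and the GC class. Clustered protocadherins, a neuronal adhesion family under SETDB1 control in other cells, had 0 of 5 members called over all genes or adjusted over the list alone, a median log2 of 5.95 (3.45 with 2 genes at their bounds), and a camera adjusted p = 0.12 with an estimated correlation and 0.0512 without unsorted replicate 3. Immediate early and heat shock genes were called lower without unsorted replicate 2 (camera adjusted p = 0.0196) and within the GC class (0.0215), but not with all libraries (5 of 31 lower and 4 higher over all genes, 7 and 4 adjusted over the list alone). Median and mean differed in sign for germline genes (−0.13 and 0.07) and ribosomal protein genes (0.09 and −0.05), and for histone genes both were negative (−0.59 and −0.45) while the test pointed up, none called.

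KRT-positive SETDB1-hairpin HCT116 cells against unsorted cells ask the same of the positive fraction. Cell division genes fell and VDR, PPAR, p53 and interferon genes rose here too. In edgeR 1232 genes were called, 566 higher and 666 lower, 1092 by at least 2-fold, against 1267 within the AT class. The GC class holds no KRT-positive library. The count was 817 without KRT-positive replicate 1 and 812 without KRT-positive replicate 3, and 30.3% of tested genes had no overlap (chance, 10%). Scaling by library totals in place of TMM moves the median of all genes from 0.08 to 0.29 and the share of called genes that are higher from 45.9% to 63.8%, so the balance of rises and falls depends on the scaling. CEACAM1 and CEACAM5, adhesion molecules whose reads their paralogs can share, were at 0 in unsorted cells and at least 116-fold and 79.8-fold higher, SELENBP1 at least 184-fold, DHRS9 at least 164-fold and DAPP1 at least 72.6-fold. TSPAN8 stood at 57.7 CPM (SD 3.59, n = 3) on 1 unsorted count, a ratio of 1030 (counting interval 184 to 40600). Interferon response genes had 10 of 32 higher over all genes and 13 adjusted over the list alone, with IFITM1 16.5-fold, the RNA sensor IFIH1 15.5-fold and ISG15 4.07-fold higher. VDR targets had 7 of 18 higher over all genes and 9 adjusted over the list alone, with CYP24A1 7.95-fold, CDH1 7.82-fold and GADD45A 4.39-fold higher. PPAR targets had 5 of 19 higher over all genes and 8 adjusted over the list alone, with ANGPTL4 6.78-fold and PLIN2 3.54-fold higher. P53 targets had 7 of 28 higher over all genes and adjusted over the list alone. Mitosis genes had 22 of 32 lower over all genes and 28 adjusted over the list alone (median log2 −2.38), with CCNB1 10.4-fold, BIRC5 8.29-fold and TOP2A 5.27-fold lower. DNA replication genes had 15 of 32 lower over all genes and 20 adjusted over the list alone, with MCM4 6.07-fold and RRM2 5.63-fold lower. FAM198B fell 411-fold and DDIAS 75.0-fold, and the cell cycle factor E2F8 was at 0 in KRT-positive cells and at least 103-fold lower, but not called without any 1 library of either group (edgeR adjusted p from 0.0829 to 0.123). These 6 lists held with an estimated correlation.

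Of the other called lists, stem cell and Wnt targets (2 of 18 lower over all genes and 4 adjusted over the list alone, DKK1 10.5-fold lower), immediate early and heat shock genes (8 of 31 lower over all genes and 10 adjusted over the list alone, IER3 8.59-fold lower), ATF4 and unfolded protein genes (9 of 27 higher and 2 lower over all genes, 14 and 5 adjusted over the list alone, CHAC1 11.4-fold higher) and ribosomal protein genes (26 of 79 lower over all genes and 41 adjusted over the list alone, RPL6 2.47-fold lower) each had a camera adjusted p = 0.081 with an estimated correlation. H3K9 methylation genes (4 of 22 lower over all genes and 5 adjusted over the list alone) had 0.0911 from camera with an estimated correlation and 0.0735 without unsorted replicate 1. Hypoxia and glycolysis genes (10 of 29 lower and 2 higher over all genes, 12 and 3 adjusted over the list alone) had 0.138 from camera with an estimated correlation. Colonocyte genes (3 of 12 higher over all genes, 4 higher and 1 lower adjusted over the list alone) were called only without KRT-positive replicate 2 (camera adjusted p = 0.0427). Protocadherins (0 of 5 over all genes, 1 higher adjusted over the list alone) were called only without KRT-positive replicate 3 (camera adjusted p = 0.0374). Cholesterol synthesis was not called (median 0.01, mean −0.37, test pointing down).

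KRT-positive against KRT-negative HCT116 cells, both with the SETDB1 hairpin, ask what separates the fractions. The positive fraction had less of SNHG5, DDIT4, ANGPTL4 and JUN and more of STIM1 and lysosomal GM2A, but few other calls were stable. In edgeR 73 genes were called, 22 higher and 51 lower, 68 by at least 2-fold, against 46 within the AT class (1 KRT-negative library) and 45 with the class as a term. The GC class holds no KRT-positive library. The count was 130 without KRT-negative replicate 1, 16 without KRT-negative replicate 2, 15 without KRT-negative replicate 3, and 17, 15 and 20 without KRT-positive replicates 1, 2 and 3, while 18.2% of tested genes had no overlap (chance, 10%). Scaling by library totals moves the median of all genes from 0.03 to 0.21 and the share of called genes that are higher from 30.1% to 49.3%. GM2A, a cofactor of ganglioside breakdown, stood at 199 CPM (SD 30.2, n = 3) against 36.5 (SD 8.29), and STIM1, the calcium sensor of the endoplasmic reticulum, was 1.52 higher on the log2 scale (edgeR adjusted p = 0.00357, higher in 3 of 3 libraries). SNHG5 was 4.82-fold lower, DDIT4 4.59-fold, ANGPTL4 5.52-fold and the early transcription factor JUN 3.84-fold lower. These 6 genes were called without each single library, and the other 23 called named genes were not. Among the latter, GCNT3, which branches mucin sugars, had 1 count in KRT-negative cells and a ratio of 1060 (counting interval 190 to 41900). ABCB1 was 5.3-fold, MYO5A 6.86-fold and LGR4 5.74-fold higher. None of these was called without KRT-negative replicate 2 or 3 or KRT-positive replicate 1 (edgeR adjusted p from 0.0501 to 0.0976). CYP24A1 was 3.66-fold lower and not called without KRT-negative replicate 2 or KRT-positive replicates 1 or 3 (edgeR adjusted p = 0.0587, 0.0748 and 0.0778), and PLIN2 2.77-fold lower and not called without KRT-negative replicate 3 or KRT-positive replicates 1 or 2 (0.0833, 0.0608 and 0.0915). HMOX1 (4.55-fold), GDF15 (2.79-fold) and the chaperone HSPA5 (1.96-fold) were lower and lost their calls without KRT-negative replicate 2 or 3 or any KRT-positive library (edgeR adjusted p from 0.079 to 0.24). ZNF419 was at 0 in KRT-positive cells and at least 207-fold lower, but not called within the AT class (edgeR adjusted p = 0.712) or without KRT-negative replicate 2 or 3 or any 1 of the KRT-positive libraries (from 0.0888 to 0.24). Ribosomal protein genes had 4 of 79 lower over all genes, 51 lower and 1 higher adjusted over the list alone (median log2 −0.64, RPS27A 2.14-fold and RPL8 2.04-fold lower). Interferon response genes had 0 of 32 over all genes and adjusted over the list alone (median 0.60). Both had a camera adjusted p = 0.0759 with an estimated correlation, and the interferon list 0.0624 without KRT-negative replicate 1. ATF4 and unfolded protein genes (2 of 27 lower over all genes and 10 adjusted over the list alone) had 0.0781 from camera with an estimated correlation. Immediate early and heat shock genes (3 of 31 lower over all genes and 7 adjusted over the list alone) had 0.27 from camera with an estimated correlation and 0.07 within the AT class. Median and mean differed in sign, with no call, for stem cell (−0.17 and 0.10), PPAR (0.20 and −0.17), VDR (−0.15 and 0.08), DNA replication (−0.02 and 0.04), H3K9 methylation (−0.07 and 0.13) and mesenchymal genes (0.15 and −0.13). For enteroendocrine genes both were negative (−0.70 and −1.34) while the test pointed up.

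KRT-negative SETDB1-hairpin SW480 cells against unsorted cells ask about SETDB1 depletion, medium again unstated, although SETDB1 was not called lower there. PPAR targets rose and DNA replication genes fell. In edgeR 281 of 13252 genes were called, 180 higher and 101 lower, 261 by at least 2-fold, against 122 within the GC class (replicates 1 and 3). The AT class holds 1 library per group and gives no test. The count was 146, 161 and 130 without KRT-negative replicates 1, 2 and 3, 155 without unsorted replicate 1 and 138 without unsorted replicate 3, and 24.5% of tested genes had no overlap (chance, 10%). FABP4, the fatty acid carrier of fat cells and a classic PPARG target, stood at 197 CPM (SD 17.5, n = 3) against 0.270 in unsorted cells, and was called without each single library. PPAR targets had 7 of 26 higher over all genes, 11 higher and 2 lower adjusted over the list alone, with TXNIP 7.02-fold and ANGPTL4 6.91-fold higher, and held with an estimated correlation. MMP19 and SLC38A4 were at 0 in unsorted cells and at least 318-fold and 119-fold higher. PPFIBP2 was at least 228-fold higher, but not called within the GC class (edgeR adjusted p = 0.056). CALB2, a calcium binder, had 2 unsorted counts and a ratio of 1310 (counting interval 363 to 10800) and REG3A, a Paneth cell lectin, 2 counts and a ratio of 234 (64.3 to 1930). CYP24A1 rose 6.16-fold to 692 CPM (SD 115) and the protease KLK6 2.34-fold, both VDR targets, of which 3 of 21 rose over all genes and adjusted over the list alone, with a camera adjusted p = 0.0532 with an estimated correlation. DNA replication had 4 of 32 lower over all genes and 12 adjusted over the list alone, and held with an estimated correlation. Its members MCM3 (2.27-fold) and FEN1 (2.31-fold lower) lost their calls without KRT-negative replicate 3 or any 1 of the unsorted libraries (edgeR adjusted p from 0.0564 to 0.121), MCM3 also without KRT-negative replicate 1 (0.107) and FEN1 without replicate 2 (0.1). Mitosis genes (2 of 32 lower over all genes and 6 adjusted over the list alone) had a camera adjusted p = 0.0784 with an estimated correlation. Stem cell and Wnt targets (3 of 22 lower over all genes, 6 lower and 2 higher adjusted over the list alone) had 0.0532 from camera with an estimated correlation. In that list the Wnt inhibitor APCDD1 was 4.83-fold lower. Immediate early and heat shock genes (3 of 30 lower over all genes and 4 adjusted over the list alone, EGR1 4.43-fold lower) had 0.18 from camera with an estimated correlation, 0.119 and 0.0511 without KRT-negative replicate 2 or unsorted replicate 3, and 0.0944 within the GC class. ZNF genes (0 of 372 higher and 1 lower over all genes, 0 adjusted over the list alone, median log2 0.43) had 0.197 from camera with an estimated correlation, and 0.0634 and 0.0776 without KRT-negative replicate 1 or unsorted replicate 1. ALDH1A3 (20.2-fold), PPA2 (56.7-fold) and the matrix protein TGFBI (14.1-fold) fell and kept their calls without each single library, but not within the GC class (edgeR adjusted p = 0.064, 0.104 and 0.0546). Colonocyte genes were called higher only without unsorted replicate 1 (camera adjusted p = 0.00303), tuft and Paneth genes only without KRT-negative replicate 3 (0.0143), unsorted replicate 1 (0.0198) or unsorted replicate 3 (0.0275), and ribosomal protein genes only without KRT-negative replicate 2 (0.0496). With no call, median and mean differed in sign for enteroendocrine (−0.69 and 0.42), germline (0.23 and −0.24), ATF4 (−0.04 and 0.02) and hypoxia genes (0.09 and −0.03). The test pointed against both for interferon (−0.04 and −0.02, test up) and cholesterol genes (0.13 and 0.03, test down).

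KRT-positive SETDB1-hairpin SW480 cells against unsorted SW480 cells add the sorted marker to that question. PPAR targets rose while stem cell and Wnt targets, mitosis genes and DNA replication genes fell, and all 4 lists held with an estimated correlation. In edgeR 460 genes were called, 252 higher and 208 lower, 428 by at least 2-fold, against 238 within the GC class. The count was 260, 285 and 219 without unsorted replicates 1, 2 and 3. Of tested genes 22.7% had no overlap (chance, 10%). Wnt and stem cell targets had 9 of 22 lower over all genes and 11 adjusted over the list alone (median log2 −1.26), among them the Wnt feedback inhibitors NKD1 (5.95-fold) and APCDD1 (4.65-fold), the stem cell factor ASCL2 (3.45-fold) and the cyclin CCND1 (2.52-fold lower). DNA replication had 9 of 32 lower over all genes and 13 adjusted over the list alone (median −0.82), with MCM2 3.59-fold and TYMS 3.96-fold lower. Mitosis genes had 5 of 32 lower over all genes and 12 adjusted over the list alone (median −1.28), with UBE2C 3.27-fold and the kinase AURKB 3.78-fold lower. PPAR targets had 7 of 26 higher over all genes, 10 higher and 1 lower adjusted over the list alone (median 0.86): FABP4 at 271 CPM (SD 80.3, n = 3) against 0.270, TXNIP 5.76-fold, and the liver factor CREB3L3, at 0 in unsorted cells, at least 139-fold higher. The chemokine CCL2 (at least 745-fold lower), the protease ADAMTS15 (at least 368-fold) and ZCCHC24 (at least 379-fold), were at 0 in KRT-positive cells. The hormone precursor UTS2B (at least 543-fold higher), SLC38A4 (at least 516-fold) and MMP19 (at least 484-fold) were at 0 in unsorted cells. REG3A had 2 unsorted counts and a ratio of 576 (counting interval 159 to 4760), the antiviral gene OASL was 173-fold, ATP2B1 3.54-fold and CDH1 2.66-fold higher, and IER3 4.64-fold lower. These genes were called without each single library. Colonocyte genes (4 of 14 higher over all genes and adjusted over the list alone, CEACAM5 117-fold higher) had a camera adjusted p = 0.112 with an estimated correlation. DPP4, 58.7-fold higher, was not called without KRT-positive replicate 2 or 3 or unsorted replicate 2 or 3 (edgeR adjusted p = 0.0513, 0.0703, 0.0782 and 0.0964). Immediate early genes (3 of 30 lower over all genes and adjusted over the list alone) had 0.0548 from camera with an estimated correlation. Ribosomal protein genes (4 of 80 lower over all genes and 10 adjusted over the list alone, median −0.28) had 0.355 from camera with an estimated correlation, and 0.0664 without KRT-positive replicate 2. VDR targets were called higher only without KRT-positive replicate 2 (camera adjusted p = 0.0373) or within the GC class (0.0138), and goblet genes only without KRT-positive replicate 3 (0.0468). With no call, median and mean differed in sign for p53 (0.05 and −0.10), mesenchymal (−0.29 and 0.13) and leukocyte and fibroblast genes (−0.65 and 0.33).

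KRT-positive against KRT-negative SW480 cells, both with the SETDB1 hairpin, ask what separates these fractions. KRT-positive cells had far more of KRT20 and less of the vitamin D enzyme CYP24A1 and of the neurotrophin receptor NGFR, and no gene list kept its call with an estimated correlation. In edgeR 59 genes were called, 30 higher and 29 lower, 58 by at least 2-fold, against 24 within the GC class. The count was 17, 29 and 7 without KRT-negative replicates 1, 2 and 3, and 32, 98 and 36 without KRT-positive replicates 1, 2 and 3. Of tested genes 17.7% had no overlap (chance, 10%). Scaling by library totals moves the median of all genes by over 0.1 and the share of called genes that are higher from 50.8% to 63.5%. CYP24A1 fell 7.48-fold (edgeR adjusted p = 0.00267), NGFR 6.18-fold, and ADAMTS15, CCL2 and ZCCHC24 to 0, while the early factor EGR1 rose 3.01-fold. These 6 were called without each single library, ZCCHC24 not within the GC class (edgeR adjusted p = 0.0906). The other 24 called named genes were not. Among them the lipid hydrolase NCEH1 was 15.5-fold higher and lost without KRT-negative replicates 1 or 3 (edgeR adjusted p = 0.073 and 0.0909), and the keratin KRT5 was 6.61-fold and KLK6 2.59-fold lower and lost without KRT-negative replicate 3 (0.0515 and 0.0629). The intermediate filament VIM was 3.58-fold lower and not called without any 1 library other than KRT-positive replicate 1 (edgeR adjusted p from 0.0664 to 0.166). Ribosomal protein genes leaned lower (2 of 80 lower over all genes and 9 adjusted over the list alone, median log2 −0.39, RPL30 2.12-fold lower), with a camera adjusted p = 0.237 with an estimated correlation. Enteroendocrine (0 of 6 over all genes and adjusted over the list alone, median 1.68), cholesterol synthesis (0 of 25, 1 higher adjusted over the list alone) and colonocyte genes (0 of 14, 3 higher adjusted over the list alone) leaned higher, and had 0.237, 0.237 and 0.243 from camera with an estimated correlation. Stem cell and Wnt targets (1 of 22 lower over all genes, 5 lower and 2 higher adjusted over the list alone), mesenchymal (1 of 23 lower, 4 lower and 1 higher adjusted over the list alone), histone (0 of 24 over all genes and adjusted over the list alone) and mitosis genes (0 of 32, 1 lower adjusted over the list alone) leaned lower, and had 0.199, 0.243, 0.243 and 0.43 from camera with an estimated correlation. Without KRT-positive replicate 3, enteroendocrine, cholesterol, colonocyte, mesenchymal, histone and mitosis genes had 0.111, 0.111, 0.182, 0.182, 0.182 and 0.184 from camera, and without KRT-negative replicate 2 cholesterol, colonocyte, mesenchymal, histone and mitosis genes 0.138, 0.0589, 0.106, 0.106 and 0.244. Without KRT-positive replicate 1 cholesterol, colonocyte and mitosis genes had 0.0519, 0.053 and 0.202 from camera, and without KRT-positive replicate 2 cholesterol and mesenchymal genes 0.058 and 0.11. Within the GC class cholesterol, mesenchymal and histone genes had 0.129, 0.106 and 0.106 from camera, and hypoxia genes were called lower (0.0311). With no call, median and mean differed in sign for H3K9 methylation (0.03 and −0.17) and ZNF genes (0.06 and −0.07), and ATF4 genes had both positive (0.10 and 0.14) while the test pointed down.

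The step from KRT-negative to KRT-positive was compared between 2 lines at a time, in a joint fit. In edgeR 145 of 14950 genes were called between Caco2 and HCT116 (89 with the difference above 0), 180 of 14809 between Caco2 and SW480 (110) and 9 of 14261 between HCT116 and SW480 (2). Library totals in place of TMM move the share above 0 from 61.4% to 41.1% and from 61.1% to 50.6%. These counts are unstable. Without any 1 Caco2 library they fall to 12 to 45 (HCT116) and 12 to 20 (SW480). They rise to 697, 231 and 263 without HCT116 KRT-negative replicates 1 or 3 or KRT-positive replicate 1, to 343 without SW480 KRT-negative replicate 2, and to 416, 665 and 442 without SW480 KRT-positive replicates 1, 2 and 3. Between HCT116 and SW480 the count runs from 5 to 53 with 1 left out. Genes named next kept calls without each single library, except HIPK2 and SEMA3C in that pair. A replicate block left no call between Caco2 and HCT116. The STIM1 rise was called in HCT116, unstably in SW480 and not in Caco2, where it was 1.47 and 2.43 less on the log2 scale. ABCB1 (2.37), GM2A (2.30) and, with 1 count in HCT116 KRT-negative cells, GCNT3 had the larger step in HCT116 than in Caco2. SNHG5 (2.47), SERINC2 (2.55) and PLIN2 (1.89) fell in HCT116, with log2 steps of 0.18, 0.45 and 0.39 in Caco2. Against SW480, TIMP3 (2.37), CYP24A1 (3.25) and TNFAIP2 (2.48) had the higher step in Caco2, and HIPK2 (2.11), ATP9A (1.61) and the fatty acid importer SLC27A2 (1.97) in SW480. Genes with a group at 0 counts (ATP6V1C2, HSD17B2, ADAMTS15, MGAT3, SEMA3C, ZNF419, S100A3) have a difference that depends on the prior count of the fit.

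Shared calls of that step were few (0 to 5 with a library left out), and genes were named after their values were seen. Each exact p takes genes as independent. Higher in Caco2 and HCT116 were GCNT3 and LGALS3, a galectin (2 genes, 0.407 expected by chance, hypergeometric exact p = 0.0618), and lower ITGB5 and SCD (2, 0.879 expected, exact p = 0.219). Higher in Caco2 and SW480 were KRT20, the sort gene, and SLC27A2 (2, 0.598 expected, exact p = 0.12). Among those lower in both were SLC2A3, TRIB2 and ZCCHC24 (4, 0.394 expected, exact p = 0.000567). Higher in HCT116 and SW480 were ABCB1, SERPINE2 and STIM1 (3, 0.0465 expected, exact p = 1.25e-05), and lower CYP24A1 and JUN (2, 0.106 expected, exact p = 0.00495). Apart from ZCCHC24, none kept both calls without each single library, and no gene was shared by all 3 lines. Within Caco2, 181 genes were higher both in differentiation medium against vehicle and in KRT20-positive against KRT20-negative cells (33.4 expected, exact p = 6.91e-95), 104 lower in both (26.2 expected, exact p = 3.77e-38) and 28 opposite. Without KRT20-positive replicates 1, 2 and 3 these were 112, 125 and 115 higher and 53, 66 and 60 lower.

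**Figure D3:**
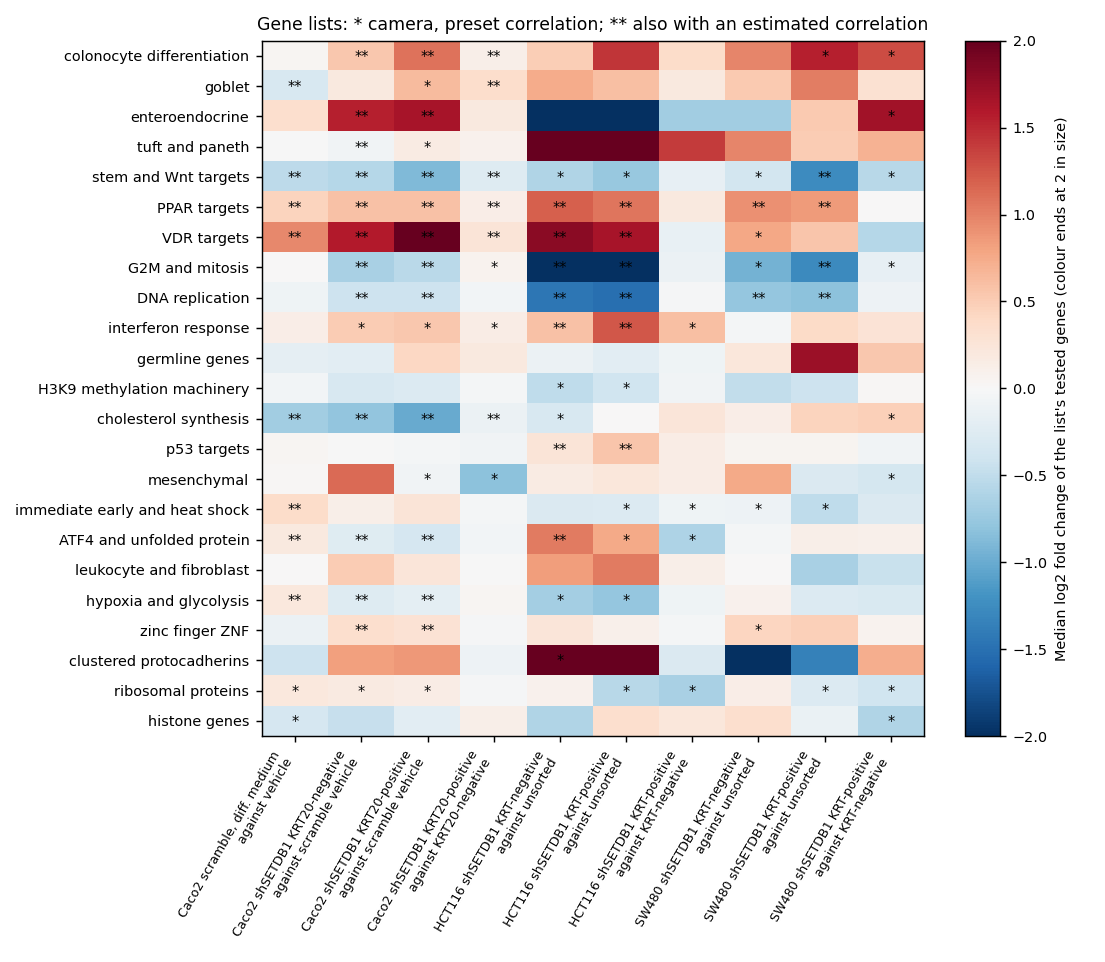
Median log2 fold change of the tested genes of each list (color, ending at 2 in size) in the 10 main comparisons. A star is a camera call with the preset correlation, 2 stars also with an estimated correlation.

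**Figure D4:**
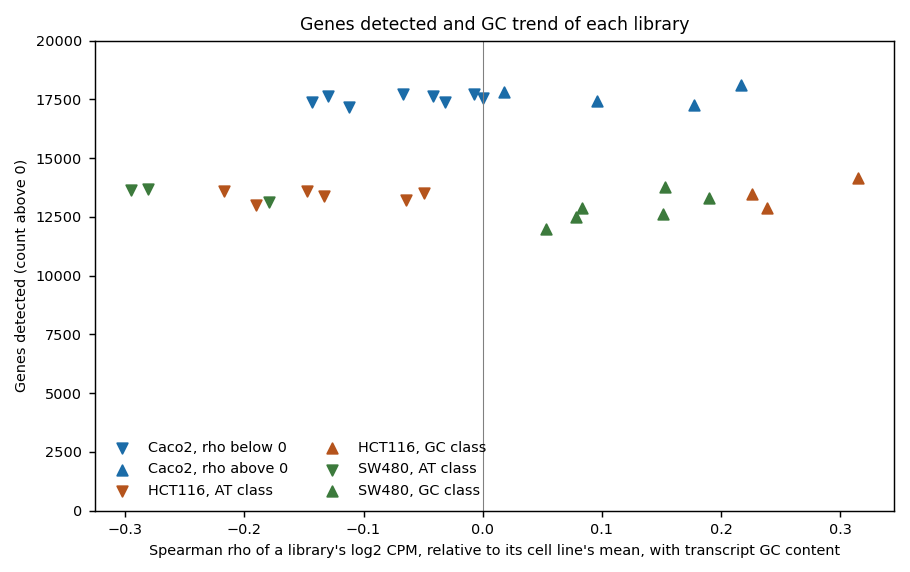
Genes detected in each library against the Spearman correlation of its levels, relative to its cell line mean, with transcript GC content. Colors are cell lines and markers the AT and GC classes.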

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

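The tests of the ribosomal protein genes within HCT116 and of the vitamin D and PPAR targets were chosen after the result was seen, as were the splits of the 12 comparisons within lines. The KRT-negative to KRT-positive step was called different between lines for 145 genes (Caco2 and HCT116), 180 (Caco2 and SW480) and 9 (HCT116 and SW480). Among 100 drawn splits of the fraction labels, 2, 2 and 4 gave as many genes, the real one included, a share under 0.05. The highest other counts were 199, 183 and 299. Most splits mix the fractions within a line, which adds spread and lowers the count whether or not the steps differ. A low share therefore does not exclude chance for a difference between lines. Those highest splits swap 1 line's labels and test the sum of both steps. A step in 1 line alone moves sum and difference alike and cannot explain 299 against 9. Without any 1 Caco2 library the first 2 counts fall to 12 to 45, and a replicate block lowers each count.

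The log2 differences, Caco2 minus HCT116, were 8.39 for STAP2, 2.47 for SNHG5, 2.55 for SERINC2, 6.67 for ATP6V1C2, 1.89 for PLIN2, −8.65 for GCNT3, −2.37 for ABCB1, −8.25 for HSD17B2, −1.47 for STIM1 and −2.30 for GM2A. Caco2 minus SW480, they were 11.69 for ADAMTS15, 2.37 for TIMP3, 3.25 for CYP24A1, 2.48 for TNFAIP2, 10.76 for MGAT3, −2.43 for STIM1, −2.11 for HIPK2, −8.50 for DLX4, −1.61 for ATP9A and −1.97 for SLC27A2. HCT116 minus SW480, they were 11.01 for SEMA3C, −8.05 for STAP2, −11.04 for ZNF419, −5.29 for LTB, −7.40 for S100A3 and −1.73 for HIPK2. Values above 5 in size involve a group at or near 0 counts and depend on the prior count of the fit.

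Ribosomal protein genes were lower in HCT116 KRT-positive than KRT-negative libraries, by a mean log2 difference of −0.578 (95% interval −0.774 to −0.381, 79 members), but the list had a camera adjusted p = 0.0759 with an estimated correlation. The GC class is uneven over these groups. With the class as a term the difference was −0.457 (−0.596 to −0.318), which argues against the class as the whole cause. In SW480, where each group holds both classes, the same genes were −0.206 in AT-class relative to GC-class libraries (−0.321 to −0.091), so part of the HCT116 value may come from the class. A difference in growth between the fractions stays open, since medians of −0.11 for mitosis and −0.02 for DNA replication genes (camera adjusted p = 0.905 for both) do not exclude it.

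Targets of VDR and PPAR were higher in KRT20-positive Caco2 SETDB1-hairpin cells than in vehicle, and the medium of those cells is not stated. If agonists acted as in scramble cells, their levels would match scramble cells in differentiation medium. The 33 members called against vehicle stood 0.998 higher on the log2 scale (95% interval 0.905 to 1.091), but their choice by a rise in the same cells builds in part of that. All 48 tested members, none chosen by its values, stood 0.698 higher (0.637 to 0.759), which argues against the agonists as the whole cause. In KRT20-negative cells the 48 also stood higher, by 0.357 (0.296 to 0.418). PPAR targets alone stood 0.181 higher there (0.114 to 0.247), but with 8 of 26 higher and 6 lower over all genes and adjusted over the list alone (camera adjusted p = 0.793), so for them this stays open. CYP24A1, at −0.112 from differentiation medium, could come from agonists in the medium, and the missing label keeps this open.

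Every comparison within a line allows 10 splits of its 6 libraries, too few for a share under 0.05, and in each only 1 split, the real one, reached the real count. The real counts were 2925, 5056, 5265, 570, 5312 and 4820 in Caco2, 1232 and 73 in HCT116 (KRT-positive against unsorted and against KRT-negative) and 281 in SW480 (KRT-negative against unsorted), with 0 as the highest other, and 460 and 59 in the other SW480 comparisons, with 1. For HCT116 KRT-negative against unsorted (698) the highest other was 47, from the split that follows the GC class, with 350 and 341 within the AT and GC classes.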

How the results depend on the processing

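The tests by GC class, and leaving out libraries in the overlaps, were chosen after seeing the data. The cause of each shift was not tested. Of 211 alternative counts of called genes 123 stayed within 1.5 times the reported count and 88 did not. Of 3296 list results 3150 were the same, 109 lost and 37 gained a call, 44 of the losses with an estimated correlation. Of 5645 named-gene results 5053 were the same, 587 lost a call (400 by leaving out a library) and 5 gained one. None of these lists or genes called in both settings reversed. The limits are the spread between HCT116 and SW480 replicates, the unstated media, and 3 samples per group.

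Comparisons come in the order of the report, and overlaps of fractions as Caco2 with HCT116, Caco2 with SW480 and HCT116 with SW480. With RLE size factors and with library totals all 15 counts stayed within 1.5 times, and of the overlaps Caco2 with HCT116 lower became 1 and 0, and with library totals Caco2 with SW480 higher became 6. With DESeq2 HCT116 counts were 1211, 1862 and 405, SW480 counts 709, 1204 and 404, differences between lines 640, 712 and 241, and overlaps 10 higher and 9 lower, 16 and 9, and 16 and 27. With no low-count filter the fractions differed by 189 genes in HCT116 and 101 in SW480, the differences were 90, 104 and 16, and overlaps 6 higher and 8 lower, 5 higher, and 6 higher and 5 lower. With only the 2 groups compared the fractions differed by 307 genes in Caco2, 126 in HCT116 and 18 in SW480, SW480 against unsorted gave 432 and 228, overlaps were 4 higher (Caco2 with HCT116) and 0 lower (Caco2 with SW480), and those with differentiation medium 119 higher and 56 lower. With the GC class as a term HCT116 fractions differed by 45 genes, SW480 gave 531, 887 and 224, and the differences of Caco2 from HCT116 and SW480 were 317 and 647. AT-class libraries only gave 350 (HCT116 KRT-negative against unsorted) and 46 (fractions), and GC-class libraries only 341 in HCT116 and 122, 238 and 24 in SW480.

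With a replicate block SW480 counts were 461, 793 and 179, edgeR called 0 genes between Caco2 and HCT116 (2203 at an unadjusted p under 0.05; DESeq2 without the block, 640), 23 between Caco2 and SW480 and 5 between HCT116 and SW480, and overlaps were 4 lower, 10 higher and 11 lower, 13 lower, and 164 lower with differentiation medium. Replicate numbers were taken not to pair, since the labels state no link and not every correlation of equal numbers is over 0.1. These run from 0.001 to 0.093 in Caco2, −0.024 to 0.074 in HCT116 and 0.006 to 0.114 in SW480, against −0.089 to 0.028, −0.152 to 0.081 and −0.077 to 0.05 for unequal numbers. A library's own number correlated best in 32 of 36, 3 of 18 and 13 of 18 cases. In Caco2 and SW480 this points to a link that the unblocked counts ignore.

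Leaving out each library in turn gave, as lowest and highest counts, 2048 and 2419, 4130 and 5261, 4426 and 4626, 297 and 651, 4448 and 5265, and 3976 and 4181 in Caco2, 395 and 730, 812 and 983, and 15 and 130 in HCT116, and 130 and 188, 219 and 510, and 7 and 98 in SW480. Differences between lines ran from 12 to 697 (without HCT116 KRT-negative replicate 1), 12 to 665 and 5 to 53 (both without SW480 KRT-positive replicate 2). Overlaps ran from 0 to 4 higher and 0 to 5 lower, 0 to 3 and 1 to 5, 0 to 3 and 1 to 3, and 112 to 191 and 53 to 116 with differentiation medium.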

Other observations

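The test of fibroblast genes in 1 library was written before its genes were looked at, and the genes of the other paragraph were chosen after their values were seen. In Caco2 KRT20-negative replicate 3, 15 of 24 listed fibroblast genes not looked at before exceeded all other 11 Caco2 libraries, where the most in any other library was 3. COL6A3 stood at 264 CPM (6.45 to 17.4 in the others), COL1A1 at 108 (11.1 to 20.6), DCN at 86.7 (3.38 to 7.61) and VIM at 34.7 (1.97 to 5.42), while the abundant fibroblast genes TAGLN (5.57, others 3.42 to 104) and IGFBP7 (124, others 124 to 178) were not higher. RNA from fibroblasts is a candidate source, which these values leave open. Of the 24 genes, 7 pass 10 CPM in the other Caco2 libraries, and a KRT20-negative gate would not remove fibroblasts.

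AFP, a fetal plasma protein, averaged 404 CPM in vehicle, 134 in differentiation medium, 4760 in KRT20-negative and 5690 in KRT20-positive Caco2 cells, and TTR, a plasma carrier, 186, 189, 1540 and 1510. The metallothionein MT2A, whose paralogs can share reads, averaged 2530 CPM in unsorted, 527 in KRT-negative and 286 in KRT-positive HCT116 cells, and 1230, 221 and 128 in SW480. PPARG averaged 4.39, 30.1 and 66.3 CPM in HCT116 and 1.02, 46.8 and 109 in SW480.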
